A study of Arabidopsis thaliana with 12 samples.

How the data were processed

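The study measured transcripts in rosette leaves of 3-week-old Arabidopsis thaliana, WT and dof2.1-KO, after 2 days with 100 µM methyl jasmonate (MeJA) or with the 3 mM MES mock solution, on 12 one-colour Agilent arrays, 3 per group. The scanner files deposited for each sample hold, per the file headers, intensity of each spot from Agilent Feature Extraction 9.1: a processed signal that is background-subtracted and detrended within the array, mean and median signals, a local background and flags of 0 or 1. The authors also deposited a series table whose name says normalized. Its values are intensity too: over 99.9% of them equal the median spot signal of 1 scanner file, with no scaling between arrays. The authors' own scaling is not given in the sources used here.

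Each scanner file was matched to a series-table column by identical values over 43549 probes spotted once. For 8 arrays both names were the same. For 4 arrays they were not: the files recorded as WT MeJA 2 and 3 carry the values of the columns dof2.1-KO mock 2 and 3, and the reverse. The next best match of any file was at most 2.66% of values. The column names put each group at 1 position on all 3 slides. Under the sample-record names WT mock and dof2.1-KO MeJA keep theirs, while WT MeJA and dof2.1-KO mock have other positions on slide 1 than on slides 2 and 3. The column names were taken as the main ones, against the plan to name each file by its sample record. The choice was made after the conflict was found and after single genes' values on each array had been seen. Gene counts, named genes and lists were also computed with the sample-record names and on the 8 arrays with 1 name. The splits, the permutation tests of DOF2.1 and the shares without overlap were not, and the size of the response was computed on the 8 arrays only.

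Spots with an outlier flag were left out (21 to 630 per array), and the log2 processed signal was taken relative to the 75th percentile of each array, with replicate spots averaged. Of the genes named, LHCB1.1, JAZ2, JAZ10, PDF1.3, PDF1.2b, SAG13, BSMT1, ANAC072 and AACT1 were left with 2 arrays in a group, and MYC2 and ACT2 with 1. In a group compared, PAP1 (WT mock), ERF1 and JUB1 (dof2.1-KO mock), LTL1 (WT MeJA), PXMT1 (WT MeJA and dof2.1-KO mock) and CYCB2-2 and AUR2 (dof2.1-KO MeJA) were well above background on 1 of 3 arrays. NYE2 and GLYI7 (mock) and SAG13 (dof2.1-KO mock) were so on 2 of 3. The sizes of these changes rest in part on signal near background. Of the genes called, 15 for MeJA in WT, 9 for MeJA in dof2.1-KO, 2 between the genotypes with MeJA and 3 for the interaction had a group of 1 array. Probes well above background on at least 3 of 12 arrays were kept, 29692 of 43603, and each gene, a locus of the probe annotation, was read by its kept probe with the highest mean, which gave 19923 genes. Gene symbols come from a table of locus tags, which holds 28595 of the 29030 loci, and no genome was given. Per array, 62.1% to 65.1% of spots were well above background, 0 to 24 were saturated, and replicate spots had a standard deviation of 0.0996 to 0.314 on the log2 scale.

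The 4 groups were fitted with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), and the contrasts were tested with moderated t-tests. Genes with Benjamini-Hochberg adjusted p under 0.05 were called, and counts at 2-fold or more are given beside. A group with no array well above background gives a bound: its signal is set at the lowest normalized signal called above background on its arrays. For the interaction a bound is given only where all such groups move it the same way. DOF2.1 was also tested by exact permutation. The size of the response was the median over called genes of the signed difference between the genotypes' responses, tested by relabelling genotype within each treatment. The 22 gene lists (jasmonate biosynthesis, catabolism, JAZ repressors, MYC and ERF branches, leaf senescence, chlorophyll breakdown and synthesis, light harvesting complexes, photosystems with electron transport and Calvin cycle, indole and aliphatic glucosinolates, flavonoids, salicylic acid, abscisic acid, cytokinin regulators, cell division, autophagy, DOF genes, circadian clock, heat shock, reference genes) and 7 marker lists (guard cells, phloem, xylem, epidermis, shoot meristem, flower, root) were fixed before any value was seen. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. All were adjusted by Benjamini-Hochberg over the lists of a kind. Fry stands for its directional test unless its mixed test is named. Genes named in the text are the largest changes, a fixed set, and the members of each list with the lowest p.

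The scripts were tested on simulated data with known changes. At a log2 change of 2, 72.7% were called for MeJA in WT and 87.9% for MeJA in dof2.1-KO. The shares were 80.3% and 72.7% for the genotypes in mock and with MeJA, and 53.0% for the interaction. At a change of 1 they were between 8.96% and 44.8%. Each run changed few genes and gave all groups the same spread, so these shares do not carry over to the MeJA comparisons. At a change of 2 each share rests on 66 genes, so differences between the pairs of groups may be chance.

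Alternatives, listed before any value was seen, were normexp background correction with an offset of 50, quantile normalization, median centring, no filter, a filter on all 12 arrays, the mean of a gene's probes, slide as a block, only the groups compared, eBayes with trend and robust, the series table's values, and each array left out. Slide, replicate number and scan part the arrays in the same way, so 1 block stands for all 3. Alternatives added later were the 2 sets of names above and the median spot signal of the scanner files. The 5190 probes without a locus were left out. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.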

Results

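DOF2.1, the gene disrupted in the mutant, was read by 1 probe that lay well above background on all 12 arrays, those of dof2.1-KO included. Its log2 signal relative to the 75th percentile of the array was 0.90, 1.26 and 0.47 in the WT mock samples, 3.08, 2.97 and 3.09 in WT with MeJA, 0.25, 0.16 and 0.49 in dof2.1-KO mock, and 0.11, 1.68 and 0.39 in dof2.1-KO with MeJA. In WT leaves DOF2.1 rose 4.50-fold with MeJA (log2 2.17, SE 0.35, n = 3 and 3, limma adjusted p = 0.000513, 0.000919 with slide as a block). On the 8 arrays with 1 name this change was 2.2 (adjusted p = 0.0452), and under the sample-record names 0.37 (adjusted p = 0.924). In dof2.1-KO its change with MeJA was 0.42 (adjusted p = 0.361). This change was -0.05 without dof2.1-KO MeJA 2 and 0.73 without dof2.1-KO MeJA 1. With MeJA, DOF2.1 was lower in dof2.1-KO than in WT (log2 -2.32, SE 0.35, adjusted p = 0.0014, 0.00263 with the block). This difference did not pass on the 8 arrays (-2.35, adjusted p = 0.101) or under the sample-record names (-0.52, adjusted p = 0.807). In mock it was -0.58 (adjusted p = 0.452). Exact permutation p-values of these 4 differences were 0.1, 0.7, 0.1 and 0.2, with 0.1 the smallest that 3 against 3 samples can give. Where the disruption lies relative to the probe is not given in the sources used here, so a signal in dof2.1-KO does not tell intact from disrupted transcript.

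**Figure D1:**
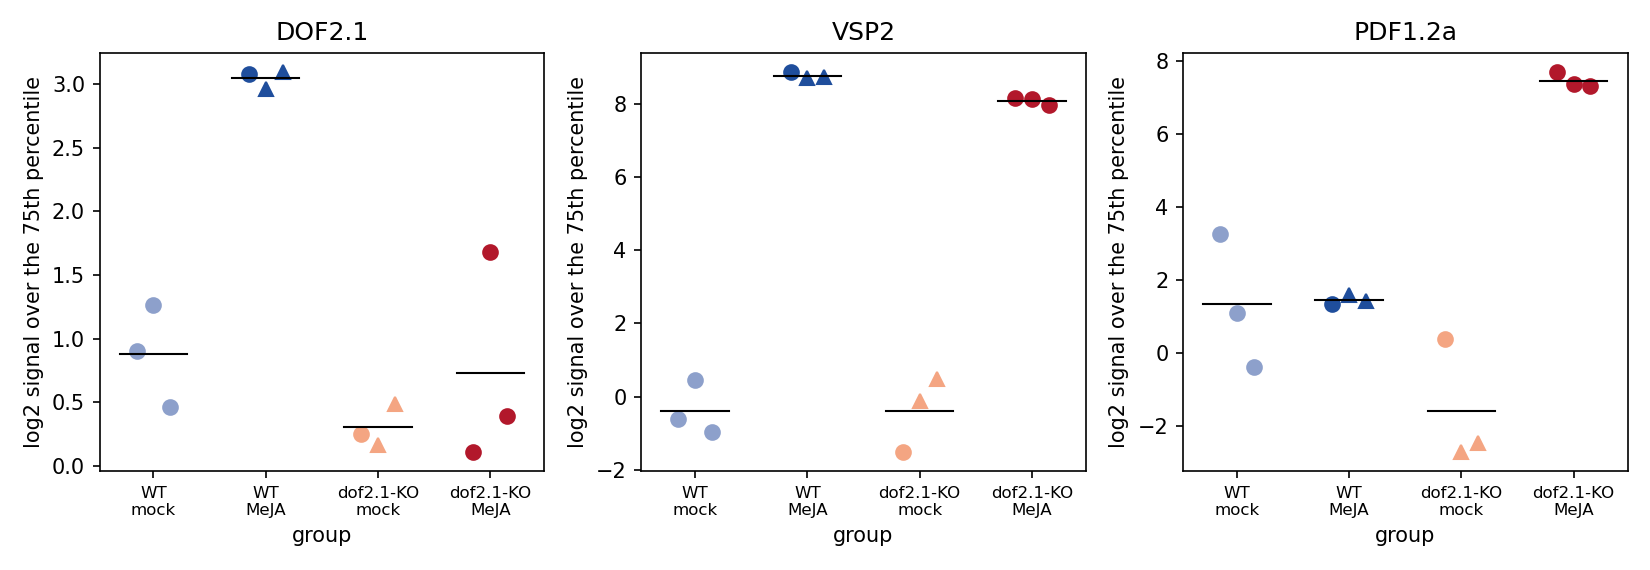
Log2 signal relative to the 75th percentile of each array for DOF2.1, VSP2 and PDF1.2a in the 4 groups. Each point is 1 array, triangles are the 4 arrays with 2 deposited names, and the line is the mean of the 3 arrays; the WT MeJA points of DOF2.1 lie between 2.97 and 3.09.

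The series table holds other values for DOF2.1 than the scanner files: 7 of its 12 values differ. With the table's values, DOF2.1 was lower in dof2.1-KO than in WT by -3.30 in mock (adjusted p = 2.68e-05) and by -6.27 with MeJA (adjusted p = 2.64e-08), and changed by -0.68 with MeJA in dof2.1-KO (adjusted p = 0.018). With the same signal column taken from the scanner files, these differences were -0.56 (adjusted p = 0.45), -2.22 (adjusted p = 0.000868) and 0.40 (adjusted p = 0.372). In all, 385 of 522588 values compared (0.0737%) differed, on 113 probes, by log2 ratios from -6.33 to 5.62. They include MYC2, ORE1, SAG13 and PDF1.2a. Among the named genes the table's values gained 9 calls and lost 5, against 3 and 5 with the scanner's median signal. All other results here rest on the scanner files.

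**Figure D2:**
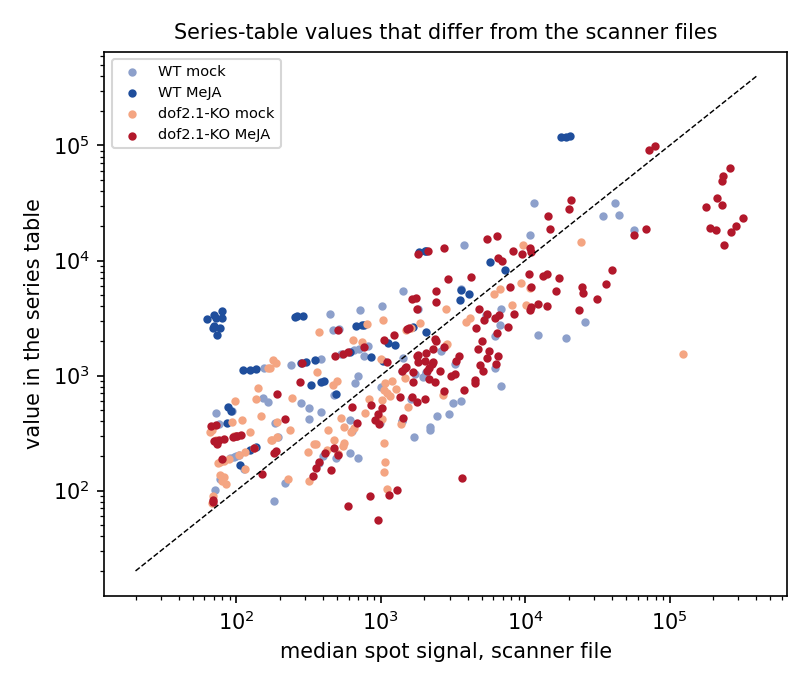
The 385 series-table values that differ from the scanner's median spot signal, each plotted against that signal on log axes in intensity units and coloured by group. Points off the dashed line of equality lie on both sides, 193 above it and 191 below it, and 1 is not a number. The sides differ by group: WT MeJA has 49 above and 0 below, and dof2.1-KO MeJA 55 and 103. WT mock has 40 and 42, and dof2.1-KO mock 49 and 46.

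For 4 arrays the deposited files give 2 names. The scanner files recorded as WT MeJA 2 and 3 hold the values of the series-table columns dof2.1-KO mock 2 and 3, and the reverse. The series-table names are used here. The counts of genes under the names of the sample records, and on the 8 arrays with 1 name, stand beside each total. List counts are given under the series-table names alone. Under the sample-record names 28 list directions turned, counting only lists called under at least 1 set of names. This choice was made after the conflict and single genes' values had been seen, and it decides most calls below. Nothing in the sources used here says whether the 3 samples of a group are separate plants, so each p-value measures only the spread between these samples. With these names each group sits at 1 position on the slide, so position and group cannot be told apart.

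In WT leaves MeJA raised most JAZ repressor, MYC branch and flavonoid genes and lowered most photosystem genes and cytokinin response regulators. BSMT1, which methylates salicylic and benzoic acid, rose at least 2533-fold, CYP81F4 of indole glucosinolate synthesis at least 1417-fold, the trypsin inhibitor gene DR4 at least 1339-fold and the thionin THI2.1 at least 867-fold. PAP1, a regulator of anthocyanin synthesis, rose by 11.98 on the log2 scale (SE 0.89, n = 3 and 3), and TT19, which carries anthocyanins to the vacuole, by 11.44 (SE 0.47). Among the largest falls were AT2G10940 (log2 -13.33, SE 1.1), the cytokinin response regulator ARR7 (at least 192-fold lower), the glutaredoxin AT4G15680 (at least 106-fold), the wax gene CER1 (at least 97.5-fold) and the cell wall gene XTH31 (at least 68.8-fold). A bound of this kind sets a group with no array well above background at the lowest signal called above it on those arrays.

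Of the jasmonate lists, all 11 measured JAZ repressors rose with MeJA in WT (median log2 2.61), with JAZ9 at 2.86, JAZ2 at 2.61 and JAZ12 at 1.93. Biosynthesis had 10 of 16 genes higher and 1 lower (median 2.04), with OPR3 at 3.06, AOS at 2.97 and AOC4 at 2.91. In jasmonate catabolism 8 of 10 rose (9 when adjusted over the list alone; median 4.90), with JOX1 at least 24.5-fold higher. The MYC branch had 13 of 15 genes higher (14 over the list alone; median 3.81): VSP2 9.14 (SE 0.47), JR1 5.49 and the transcription factor MYC2 3.81 (SE 0.29). The ERF branch had 2 of 9 higher, THI2.1 and the chitinase CHIB (7.10), while 7 did not pass, among them the defensin PDF1.2a (0.12, SE 0.92, adjusted p = 0.919). Its median was 0.12 and its mean 2.32, and the medians on slides 1 to 3 were -1.75, 0.48 and 1.81. The camera test with a preset correlation called JAZ repressors (adjusted p = 1.55e-06, or adjusted p = 0.146 with an estimated correlation) and the MYC branch (adjusted p = 1.15e-07, or adjusted p = 0.0376 with an estimated correlation).

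Leaf senescence genes moved both ways in WT: 10 of 30 rose and 6 fell (median 0.24). SAG29, a sugar transporter gene, rose at least 249-fold and DIN2 at least 24.2-fold, SAG13 by 6.07 (SE 0.80), the senescence regulator ORE1 by 3.31 (SE 0.65) and WRKY45 by 4.37; SAG12 was not well above background on any array. Chlorophyll breakdown had 10 of 14 higher and 2 lower (median 1.94): NYE2 8.37, the pheophytinase PPH 3.29, PAO 2.72 (SE 0.18) and NYE1 1.84 (SE 0.23). Chlorophyll synthesis had 19 of 20 lower (median -1.83; CHLH -2.65, CHLD -2.04), light harvesting complexes 17 of 20 (median -0.96; LHCB2.3 -6.77, LHCB4.3 -5.12, LHCB1.1 -1.60) and photosystems, electron transport and Calvin cycle 34 of 36 (median -1.31; RBCS3B -2.19, PSAG -1.80). LHCB1, RBCS and PDF1.2 genes have close paralogs, and their probes may read more than 1 gene.

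Flavonoid and anthocyanin genes had 18 of 21 higher and 1 lower in WT (median 6.08), among them UF3GT at least 533-fold, MYB113 at least 253-fold and LDOX at least 182-fold. Indole glucosinolate and tryptophan genes had 9 of 18 higher (10 over the list alone) and 5 lower (median 0.64; MYB34 2.87, TSB2 2.56), and aliphatic glucosinolate genes 1 higher and 6 lower of 15 (median -0.97; MYB29 -4.02). Salicylic acid response had 8 of 15 lower (9 over the list alone, median -1.45). ICS1, a gene of salicylic acid synthesis, stood at -4.40, PR5 at -3.97 and PAD4 at -3.50. Abscisic acid response had 10 of 19 higher and 2 lower (median 1.42; ABI1 2.97, RAB18 2.66). All 8 cytokinin response regulators fell (median -5.78), with ARR6 at least 20.4-fold and ARR4 -6.07. Epidermis markers moved with these groups: 6 of 7 fell (median -2.15; ATML1 -2.81, FDH -2.15), as did 5 of 7 guard cell genes with 1 higher (median -1.37) and 4 of 5 xylem genes (median -1.31), while 3 of 4 phloem genes rose (median 0.57).

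In total 10946 of 19914 genes changed with MeJA in WT, 5206 higher and 5740 lower, 6692 of them at least 2-fold; the count was 11346 with slide as a block. It was 5816 on the 8 arrays with 1 name and 0 under the sample-record names (1467 at unadjusted p under 0.05). The 3 MeJA values lay wholly above or below the 3 mock values for 62.0% of genes, against 10% by chance. Camera called 13 of 22 lists with the preset correlation and 1 with the estimated one.

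In dof2.1-KO leaves MeJA raised all 9 ERF branch genes, of which 2 had passed in WT. The defensins PDF1.2a (log2 9.07, SE 0.92, n = 3 and 3) and PDF1.2c (9.21, SE 0.83), known for defence against fungi, rose over 500-fold. THI2.1 rose at least 772-fold, DR4 at least 1223-fold, CYP81F4 at least 516-fold and DFR of anthocyanin synthesis at least 758-fold. The auxin-responsive SAUR68 was at least 93.3-fold lower, ARR7 at least 213-fold, the glutaredoxin AT3G21460 at least 182-fold, and AT2G10940 fell to -12.50 (SE 1.1).

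All 9 ERF branch genes rose with MeJA in dof2.1-KO (median log2 9.07, and 7.0, 10.09 and 9.81 on slides 1 to 3; camera adjusted p = 3.4e-08, or adjusted p = 0.127 with an estimated correlation). JAZ repressors had 9 of 11 higher and 1 lower (median 2.48; JAZ5 5.21, JAZ2 2.48, camera adjusted p = 2.36e-05, or adjusted p = 0.127 with an estimated correlation), jasmonate biosynthesis 10 of 16 higher and 1 lower (median 2.1; AOC2 4.46, OPR3 3.16, adjusted p = 0.293 with an estimated correlation), catabolism 4 of 10 (median 1.91; JOX1 at least 8.52-fold, adjusted p = 0.5 with an estimated correlation) and the MYC branch 12 of 15 (13 over the list alone; median 3.18; VSP2 8.47, JR1 4.34). MYC2, counted there, stood at 3.40 on the 1 MeJA array that outlier spots left it. Senescence genes had 11 of 30 higher and 2 lower (13 and 3 over the list alone; median 0.54; SAG13 6.19), while ORE1 (1.57, SE 0.65, adjusted p = 0.0724) did not pass. Chlorophyll breakdown had 11 of 14 higher and 2 lower (median 0.85; NYE2 6.07, PAO 1.3, NYE1 0.79). Chlorophyll synthesis had 19 of 20 lower (median -1.72; HEMA1 -3.46, CAO -2.63), light harvesting complexes all 20 (median -1.84; LHCB3 -3.14, LHCB1.1 -2.45) and photosystems and Calvin cycle all 36 (median -1.19; PSAG -1.84).

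Flavonoid genes had 16 of 21 higher in dof2.1-KO (median 5.87; UF3GT at least 304-fold, LDOX at least 113-fold), indole glucosinolate and tryptophan genes 12 of 18 (median 1.31; TSB2 2.6, CYP83B1 2.24) and aliphatic glucosinolate genes 2 higher and 2 lower of 15 (1 lower over the list alone). Salicylic acid response had 1 of 15 higher, PR2 (3.00, SE 0.86), and none over the list alone; its median was -0.20 and its mean 0.10. Abscisic acid response had 6 of 19 higher and 1 lower (median 0.17; RAB18 3.70, ABI1 2.09). All 8 cytokinin response regulators fell (median -5.77; camera adjusted p = 1.65e-08, or adjusted p = 0.0399 with an estimated correlation). Cell division genes, with 2 of 19 higher in WT (0 over the list alone), had 7 lower and 3 higher in dof2.1-KO (median -0.50, and -1.27, 0.46 and -0.91 on slides 1 to 3; CYCB1-2 -1.80, KNOLLE -1.79), and DOF transcription factors, with 10 of 22 higher and 2 lower in WT, had 9 lower (median -0.51, and -0.51, 0.08 and -0.88 on slides 1 to 3; CDF5 -2.51). Among the markers that moved with them, 2 of 4 phloem genes fell (SEOR1 -1.82), as did 6 of 7 epidermis, 5 of 7 guard cell and all 5 xylem genes.

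In dof2.1-KO 8895 of 19913 genes changed with MeJA, 3993 higher and 4902 lower, 5227 of them at least 2-fold, and 9227 with slide as a block. The count was 3699 on the 8 arrays with 1 name and 142 under the sample-record names. Values did not overlap for 60.0% of genes, against 10% by chance. Of the genes higher in WT, 2976 were also higher in dof2.1-KO (1043 by independent lists), and of those lower 3538 were also lower (1412 by independent lists). Camera called 13 of 22 lists with the preset correlation and 2 with the estimated one.

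Without MeJA the genotypes differed in 3 genes, all lower in dof2.1-KO. CYP71A12, a gene of camalexin and indole defence compounds, was at least 6.39-fold lower (adjusted p = 0.000809), the invertase gene A/N-InvF at least 2.13-fold (adjusted p = 0.0324, 0.0605 with slide as a block) and PPI2, a proton pump interactor gene, at least 1.01-fold (adjusted p = 0.000784). PPI2 lies outside the rule for named genes and is given because the count is 3. Other named genes did not pass: ERF1 was at -3.49 (adjusted p = 0.128), JUB1 at -4.13 (adjusted p = 0.127), PDF1.3 at -3.12 (adjusted p = 0.153), PDF1.2a at -2.94 (adjusted p = 0.174), EDS5 at -2.65 (adjusted p = 0.134) and HSP90-1 at -2.15 (adjusted p = 0.138). VSP2 (-0.01), MYC2 (-0.20), PAO (-0.01), NYE1 (-0.30), ORE1 (-0.26), SAG13 (-1.92) and LHCB1.1 (0.22) did not pass either.

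No member of any list or marker list passed across all genes in the mock comparison. Over the list alone, 9 of 15 salicylic acid response genes (median -1.80) and 8 of 30 senescence genes (median -0.50) were lower in dof2.1-KO. So were 6 of 9 ERF branch genes (median -2.70) and 5 of 7 heat shock genes (median -1.04). Cytokinin response regulators went the other way, with 2 of 8 higher (median 0.56). Camera called 9 of 22 lists with the preset correlation, the salicylic acid list at adjusted p = 2.51e-09, or adjusted p = 0.395 with an estimated correlation. Of the 9, cytokinin response regulators (camera adjusted p = 0.0234) and DOF genes (camera adjusted p = 0.048) were called higher. No list was called with the estimated correlation or with fry's directional test. Fry's mixed test, for changes either way, called leaf senescence (adjusted p = 0.0259) and the ERF branch (adjusted p = 0.038). It also called indole glucosinolates, salicylic acid response and cytokinin response regulators (each adjusted p = 0.0351). At unadjusted p under 0.05, 3379 of 19911 genes differed, or 1610 when only the mock arrays were fitted. Values did not overlap for 15.7% of genes, against 10% by chance. The main fit takes 1 spread per gene from mock and MeJA arrays alike. The WT mock arrays differed from each other by standard deviations of 0.81 to 0.93 on the log2 scale, the WT MeJA arrays by 0.33 to 0.50. The sample-record names gave 3 genes and the 8 arrays 4, none of them among the 3 above, and leaving out WT mock 3 gave 1926.

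With MeJA dof2.1-KO had more defensin transcript than WT, and all 4 phloem markers, 11 of 19 cell division genes and 7 of 14 chlorophyll breakdown genes were lower. The defensins PDF1.2b (log2 6.48, SE 1.1), PDF1.3 (6.47, SE 0.89), PDF1.2c (6.42, SE 0.83) and PDF1.2a (6.01, SE 0.92) were higher, with n = 3 and 3 for PDF1.2a and PDF1.2c and 2 dof2.1-KO arrays against 3 for PDF1.2b and PDF1.3, as were AACT1 (at least 94.8-fold), the cadmium resistance gene PCR1 (at least 96.5-fold) and the lipase LTL1 (5.8, SE 0.58). Lower in dof2.1-KO were SAG29 (-6.73, SE 0.45), AT4G10290 (-6.54, SE 0.63) and BSMT1 (-5.49, SE 0.77). The terpene synthase TPS10 was lower too, but was well above background on 1 of 3 dof2.1-KO arrays, so no size is given.

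In the ERF branch 5 of 9 genes were higher in dof2.1-KO with MeJA (median 3.19, and 1.62, 2.65 and 3.09 on slides 1 to 3; camera adjusted p = 0.00264, or adjusted p = 0.574 with an estimated correlation). The other jasmonate lists had only lower members: 4 of 11 JAZ repressors (6 over the list alone; median -0.78; JAZ10 -2.93, JAZ9 -0.97), 3 of 16 biosynthesis genes (2 over the list alone; median -0.62; JMT -2.42, KAT2 -0.94), 2 of 10 catabolism genes (JOX1 -1.47 among them) and 4 of 15 MYC branch genes (median -0.68; ANAC072 -3.31, JR1 -1.27). VSP2 (-0.68, adjusted p = 0.316) did not pass, and MYC2 (-0.61) had 1 dof2.1-KO array, which is no test. Senescence genes had 10 of 30 lower (median -0.49; WRKY57 -1.48; ORE1 -2.00, SE 0.65, adjusted p = 0.0455), with SAG13 (-1.80, adjusted p = 0.0948) not passing. Chlorophyll breakdown had 7 of 14 lower and 1 higher (median -1.0, camera adjusted p = 0.00264, or adjusted p = 0.317 with an estimated correlation): PAO -1.43 (SE 0.18, adjusted p = 0.000485), PPH -1.43, NYE1 -1.35 (SE 0.23) and NYC1 -1.18. Light harvesting complexes had 13 of 20 lower (15 over the list alone) and 2 higher (median -0.63; LHCB2.1 -1.47, LHCB4.3 3.60; LHCB1.1 -0.63, adjusted p = 0.0197, 0.0776 with slide as a block). Photosystems and Calvin cycle had 9 of 36 higher and 5 lower (10 and 7 over the list alone; median -0.09, mean 0.09; RBCS2B 1.16, RBCS3B 1.05) and chlorophyll synthesis 4 of 20 higher and 2 lower.

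Cell division genes had 11 of 19 lower in dof2.1-KO with MeJA (12 over the list alone; median -1.48; AUR2 -2.79, CYCB2-2 -2.54, KNOLLE -2.26, CYCB1-2 -2.25, camera adjusted p = 0.000268, or adjusted p = 0.574 with an estimated correlation). All 4 phloem markers were lower beside them (median -1.28, and -1.35, -1.13 and -1.36 on slides 1 to 3; camera adjusted p = 0.000886, or adjusted p = 0.101 with an estimated correlation): the sieve element protein gene SEOR1 -1.68, PP2A1 -1.32, the phloem regulator APL -1.24 and the sucrose transporter SUC2 -0.88. DOF transcription factors had 8 of 22 lower, DOF2.1 itself, DOF5.6 (-2.54, SE 0.31), DOF5.3 (-2.45, SE 0.23) and CDF1 (-1.33) among them. Epidermis markers had 4 of 7 higher and 1 lower (median 0.82; ATML1 1.45, FDH 0.82) and guard cell markers 3 higher and 1 lower (KAT1 -1.80); no xylem, flower or root marker passed. Abscisic acid response had 6 of 19 lower (7 over the list alone) and 1 higher (median -1.03; ABI1 -1.48, HAB1 -0.83), flavonoids 4 of 21 lower (1 over the list alone; PAL1 -1.86, PAP2 -1.29), and salicylic acid response 2 of 15 higher (CBP60g 2.39, PR5 1.97). Indole glucosinolate genes had 1 of 18 higher (MYB122, at least 1.99-fold) and 2 lower, aliphatic glucosinolate genes 1 of 15 each way (0 lower over the list alone), and cytokinin response regulators 3 of 8 higher and 1 lower.

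In total 5099 of 19919 genes differed between the genotypes with MeJA, 2391 higher and 2708 lower in dof2.1-KO, 2645 of them at least 2-fold, and 5463 with slide as a block. The count was 8568 when only the 6 MeJA arrays were fitted, 700 on the 8 arrays with 1 name and 208 under the sample-record names; 65 of those 208 were higher. Leaving out 1 array gave from 2999 (without dof2.1-KO MeJA 3) to 6004 (without WT mock 1). Which direction prevailed hung on the processing: 46.9% of the called genes were higher, and 53.5% with quantile normalization. The share was 34.5% with the scanner's median signal, another signal column scaled in the same way. Values did not overlap for 58.1% of genes, against 10% by chance, and camera called 12 of 22 lists with the preset correlation and 0 with the estimated one.

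The defensins were among the genes whose response to MeJA itself differed most between the genotypes. The interaction, response in dof2.1-KO minus response in WT, was 9.59 for PDF1.3 (SE 1.19), 9.53 for PDF1.2b (SE 1.47), 9.12 for PDF1.2c (SE 1.18), 8.95 for PDF1.2a (SE 1.3) and 9.26 for PXMT1 (SE 1.09), and -6.40 for the glyoxalase GLYI7 (SE 1.52). With a group not well above background, it was a bound for AACT1 (at least 1886-fold) and the wall-associated kinase WAK3 (at least 87.7-fold), both positive, and for AT5G33355 (at least 76.1-fold, negative). TPS10 and SAG29 (negative) and MYB122 (positive) were called, but their dim groups leave the size without a bound. All 4 phloem markers had a negative interaction (SEOR1 -1.91, PP2A1 -1.33, APL -1.26, SUC2 -0.86), as had 7 of 22 DOF genes (9 over the list alone; DOF5.6 -2.87, DOF5.3 -2.83, CDF1 -2.25) and 7 of 19 cell division genes (CYCB1-2 -2.19, KNOLLE -2.13). The cell division medians were -1.71, 0.40 and -2.06 on slides 1 to 3, so slide 2 went the other way.

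Chlorophyll breakdown had a negative interaction in 4 of 14 genes (7, and 1 positive, over the list alone): PAO -1.42 (SE 0.25, adjusted p = 0.00737), PPH -1.40 and NYC1 -1.34 passed, and NYE1 (-1.05, adjusted p = 0.0648) did not. The ERF branch had 6 of 9 positive (7 over the list alone; median 5.3, and 4.85, 6.16 and 4.98 on slides 1 to 3; camera adjusted p = 1.68e-05, or adjusted p = 0.474 with an estimated correlation). Light harvesting complexes had 7 of 20 negative (14 over the list alone) and 2 positive (LHCB1.1 -0.85, adjusted p = 0.0399, 0.129 with slide as a block; LHCB4.3 3.92), chlorophyll synthesis 3 negative and 1 positive (HEMA1 -1.65), and photosystems and Calvin cycle 1 negative and 3 positive (2 and 5 over the list alone; RBCS3B 1.0). JAZ repressors had 3 of 11 negative (4 over the list alone; JAZ10 -3.11, JAZ3 -1.56, JAZ9 -1.37), biosynthesis 2 of 16, catabolism 1 of 10 (2 over the list alone) and the MYC branch 2 of 15 (3 over the list alone; ANAC072 -4.33, JR1 -1.14). Senescence genes had 2 positive and 3 negative of 30 (JUB1 6.05), and indole glucosinolate genes 5 positive and 2 negative of 18 (7 and 3 over the list alone). CYP81F2 stood at 7.38 and MYB51 at 5.24. The indole glucosinolate median between the genotypes was -0.53 in mock, where no member passed across all genes. With MeJA it was 0.06, with 1 member higher in dof2.1-KO, MYB122, and 2 lower. Salicylic acid response had 2 positive of 15 (6 over the list alone), with CBP60g at 4.54 and PR5 at 3.77. Its median between the genotypes was -1.80 in mock, where no member passed across all genes, and 0.07 with MeJA. JUB1 too was lower in dof2.1-KO mock without passing. VSP2 (-0.67, adjusted p = 0.551), ORE1 (-1.74, adjusted p = 0.239) and SAG13 (0.12, adjusted p = 0.954) did not pass, and MYC2 (-0.41) had 1 dof2.1-KO MeJA array.

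**Figure D3:**
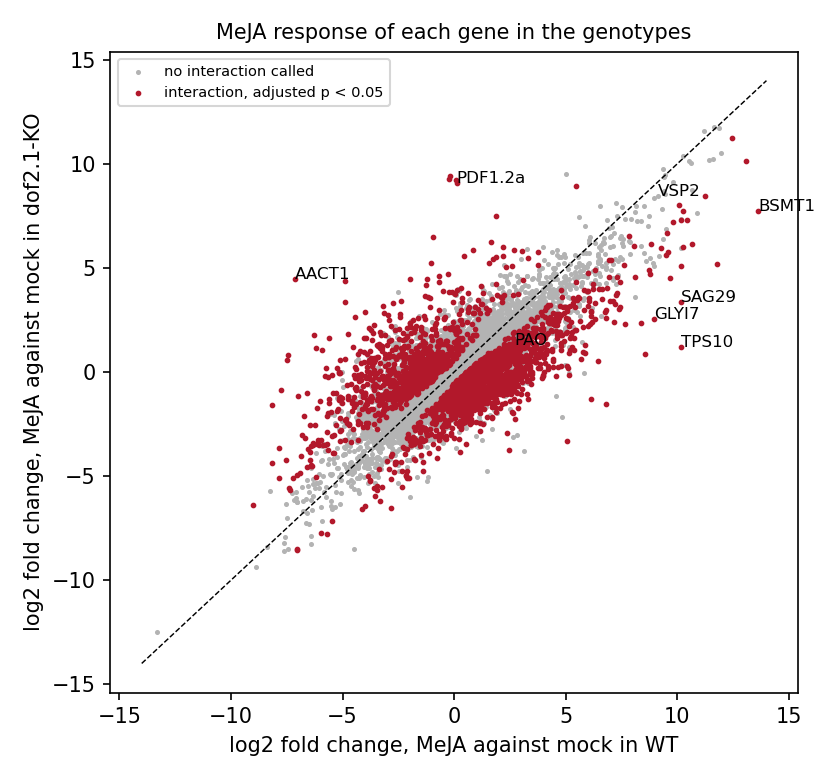
Log2 fold change with MeJA in WT (x axis) and in dof2.1-KO (y axis), 1 point per gene, with the 2573 genes called for the interaction in red. PDF1.2a lies far above the line of equality and GLYI7 below it. Points with a group not well above background, TPS10 and SAG29 among them, stand at fitted values.

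The interaction was called for 2573 of 19910 genes, 996 positive and 1577 negative, and 2613 with slide as a block. Of these, 221 were bounds and 220 had no bound. Leaving out 1 array gave from 1338 (without WT MeJA 3) to 3876 (without WT mock 3). On the 8 arrays with 1 name it was called for 13 genes (2897 at unadjusted p under 0.05), and under the sample-record names for 1 (2306 at unadjusted p under 0.05), although the estimates of genes with a value on all arrays are the same under both sets of names. Of genes that rose on average 878 had a negative and 133 a positive interaction, and of genes that fell 573 had a positive and 325 a negative one, with 664 not called for the mean effect. Camera called 11 of 22 lists with the preset correlation and 0 with the estimated one. With the scanner's median signal 27.4% of the called genes were positive against 38.7%, with a median of all genes at -0.12.

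Averaged over the genotypes, 12134 of 19910 genes changed with MeJA (5705 higher, 6429 lower; 5894 at least 2-fold; 12469 with slide as a block, 7459 on the 8 arrays, 0 under the sample-record names). Over those 5894 genes the response was smaller in dof2.1-KO by a median of -0.38 on the log2 scale (permutation p = 0.105 over 400 relabellings of genotype, of which the smallest possible is 0.005). The median response was 1.97 in WT and 1.57 in dof2.1-KO. The difference was -0.52 for rising genes (permutation p = 0.09) and, signed by direction, -0.29 for falling genes (permutation p = 0.18), and 65.4% of genes had the smaller response in dof2.1-KO (permutation p = 0.385).

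**Figure D4:**
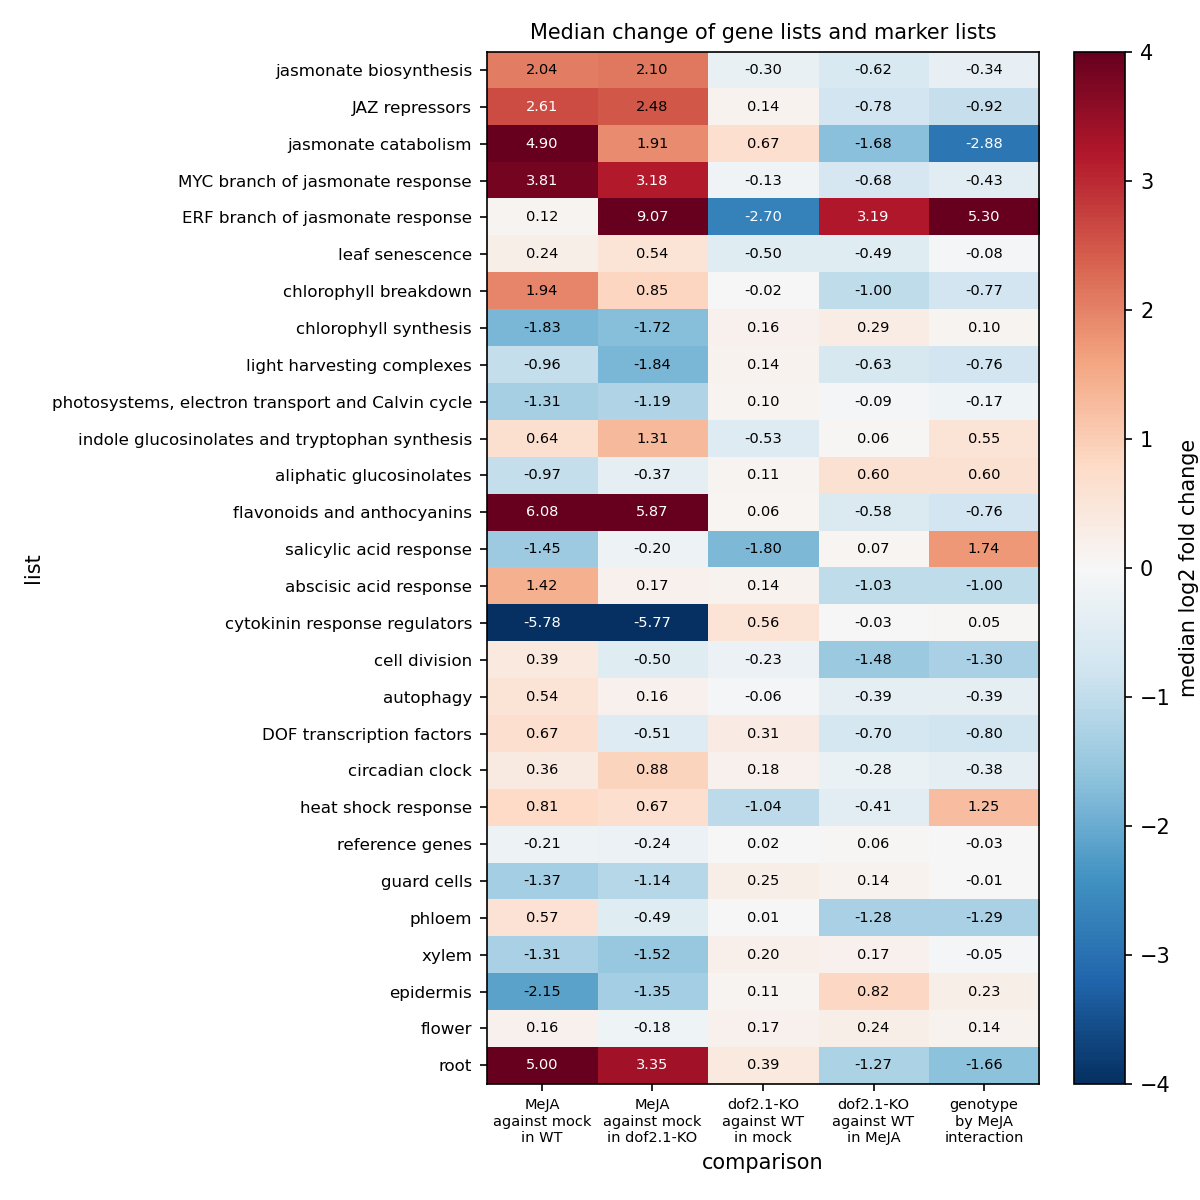
Median log2 fold change of each gene list and marker list (rows) in the 5 comparisons (columns), printed in each cell and coloured from blue (lower) to red (higher). The ERF branch stands at 0.12 with MeJA in WT and 9.07 in dof2.1-KO, and the phloem markers at 0.57 and -0.49.

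**Figure D5:**
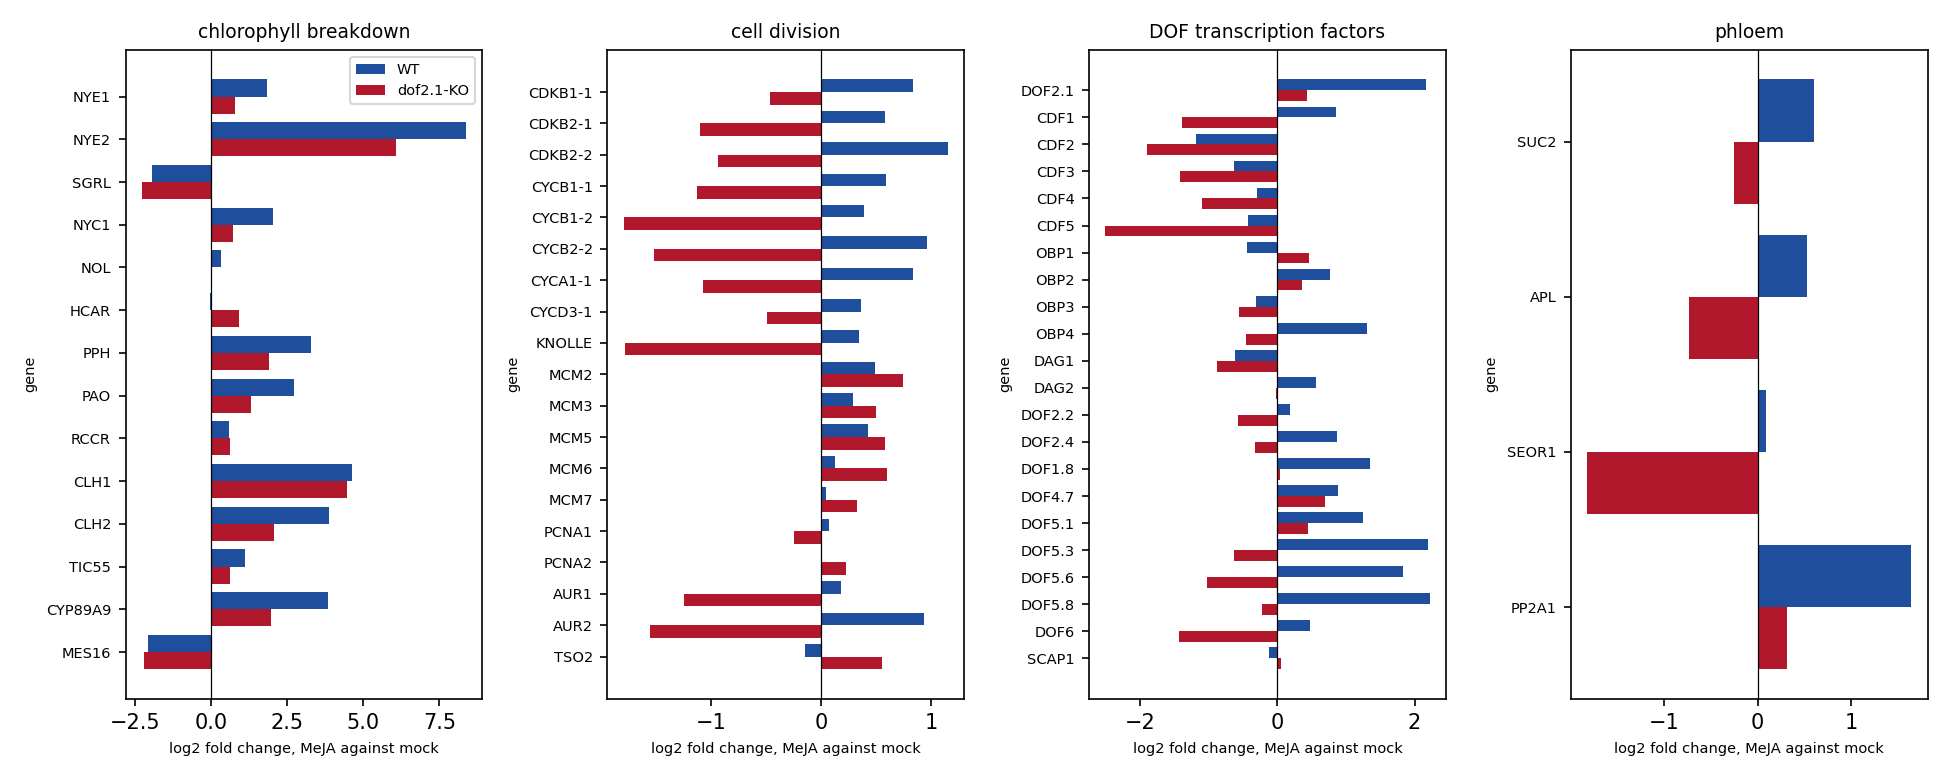
Log2 fold change with MeJA for each member of 4 lists, with WT in blue and dof2.1-KO in red. For the phloem marker SEOR1 the bars stand at 0.09 in WT and -1.82 in dof2.1-KO.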

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

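The tests of array names, of the ERF branch, and of the series table against other signal columns and the gene lists were chosen after the values they concern had been seen, as were the counts of round and of 1-way differences. The test of outlier and saturated spots and the splits were written down before they were run. The MeJA response differed between the genotypes in 2573 genes. Of 100 splits of the arrays by genotype within treatment, the real one included, 4 gave as many interaction genes (highest other 3839). The other splits were drawn at random and without regard to slide. The share is under 0.05, but other splits called 2865, 3104 and 3839 genes, and another called 2556. A split can keep the genotypes of the MeJA arrays apart and mix only the mock arrays. A genotype difference with MeJA then enters it. Among the MeJA arrays alone the real split called 5099 genes and the highest other 1. Which large splits are of this kind was not recorded, so the splits are no clean measure of chance. The count alone is thus thin ground for setting aside chance or another structure among the arrays. For the mean MeJA effect 1 of 100 splits gave as many as the real 12134 genes (highest other 4974). With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real counts were 10946 for MeJA in WT (1 split as large, highest other 2), 8895 in dof2.1-KO (1, highest other 2), 5099 between the genotypes with MeJA (1, highest other 1) and 3 between them in mock (2, highest other 698). A split of the mock arrays that calls 698 genes points to a structure among those arrays other than genotype.

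Lists whose interaction camera called had these median log2 values: JAZ repressors -0.92, jasmonate catabolism -2.88, ERF branch 5.3, chlorophyll breakdown -0.77, light harvesting complexes -0.76, indole glucosinolates 0.55, flavonoids -0.76, salicylic acid response 1.74, cell division -1.30, autophagy -0.39, DOF genes -0.80 and phloem -1.29. None was called with an estimated correlation, where the lowest adjusted p was 0.123, for phloem. The ERF branch, salicylic acid and indole glucosinolate values rest in part on mock, where the medians between genotypes were -2.70, -1.80 and -0.53. With MeJA the indole glucosinolate median between genotypes was 0.06, and the mean 0.53. Named genes with an interaction were AACT1 (at least 1886-fold), PDF1.3 9.59, PDF1.2b 9.53, PDF1.2c 9.12, PDF1.2a 8.95, PXMT1 9.26, WAK3 (at least 87.7-fold), CYP81F2 7.38, JUB1 6.05, MYB51 5.24, CBP60g 4.54, LHCB4.3 3.92, PR5 3.77 and RBCS3B 1.0 on the positive side. On the negative side were AT5G33355 (at least 76.1-fold), GLYI7 -6.40, ANAC072 -4.33, JAZ10 -3.11, DOF5.6 -2.87, DOF5.3 -2.83, CDF1 -2.25, CYCB1-2 -2.19, KNOLLE -2.13, SEOR1 -1.91, HEMA1 -1.65, JAZ3 -1.56, PAO -1.42, PPH -1.40, JAZ9 -1.37, NYC1 -1.34, PP2A1 -1.33, APL -1.26, JR1 -1.14, SUC2 -0.86 and LHCB1.1 -0.85.

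Names of 4 arrays. If the sample records carry the wrong names, the 4 arrays should correlate most with the 1-name array of the group the series table gives, and the lowest such correlation was 0.955. If the series table carries the wrong names, they should correlate most with the array of the record's group, and the highest such correlation was 0.797. Of the 2 sets of names the values thus argue against the sample records. How the conflict arose is not given in the sources used here, and a test of names by values is not independent of the results it changes.

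Higher ERF branch in dof2.1-KO with MeJA. Scaling would lower the list's median to under 1 with another method, and the lowest over quantile normalization, median centring and normexp was 2.96. A slide effect would remove it on some slide, and the lowest of the 3 slides alone was 1.62. The names of 4 arrays would bring some dof2.1-KO MeJA array within 1 of an array that either set of names gives to WT MeJA, and the lowest such median was 1.62 of 15 pairs. That lowest pair was dof2.1-KO MeJA 1 against WT MeJA 1, arrays with 1 name each. Against WT MeJA 1, dof2.1-KO MeJA 2 and 3 stood at 3.26 and 3.29. The difference thus stood without the 4 arrays, though against 1 WT array. Pairs with the arrays that only the sample records name WT MeJA ran from 7.05 to 10.09. Those arrays correlate most with mock, so these pairs could hardly have come under 1 and decide nothing. The 75th percentiles of the arrays ran only from 643 to 1026, so a shift of whole arrays could hardly have brought the median under 1. Each slide carries all 4 groups, so an effect common to a slide cancels within it. The tests of scaling and slide thus show only that the difference stood with each method and on each slide. A difference in position on the slide or in the plants' handling was not tested and cannot be told from genotype here.

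Series-table values that differ from the scanner files, 385 in number. Of them 0% equal the mean or processed signal of the spot, and 2.34% lie on outlier or saturated spots, so neither another signal column nor a correction of bad spots accounts for them. Errors spread at random over probes would fall on the fixed gene lists as often as other probes do, yet 50% of differing probes with a locus lie on them, against 1.61% of all others (Fisher p = 1.24e-65). They differ by a multiple of 10 in 91.7% of cases, against 5.58% of differences between 2 arrays of a group, and where 2 or 3 arrays of a group differ on a probe, 87.4% go 1 way, against 35.7% if each went either way. How the values arose cannot be told from the files.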

How the results depend on the processing

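Which array names to use, and the scanner's median signal as an alternative, were chosen after results had been seen, and all other alternatives were fixed before. The names decide most calls. Under the sample-record names 0 genes changed with MeJA in WT, 142 in dof2.1-KO and 0 on average, 208 differed between genotypes with MeJA, and 1 had an interaction. On the 8 arrays with 1 name these were 5816, 3699, 7459, 700 and 13, with 1 WT MeJA and 1 dof2.1-KO mock array assumed to vary like the other groups. With slide as a block, equal to replicate number and scan, the counts were 11346, 9227, 12469, 5463 and 2613, and 2 in the mock comparison. The block ended 6 calls of named genes and 1 call of a list, and added 1 call of a list. Under the sample-record names 167 calls of named genes ended, and 23 more turned direction. Over all fits with 1 array left out, 87 calls of named genes ended and 10 were added. Replicate numbers were not shown to pair the samples across all 3 numbers: correlations of residuals within a number ran from -0.20 to 0.49 (median 0.10), over 0.1 in 9 of 18, and 6 of 12 arrays fitted best with their own number. Number 1, the slide with 262 to 630 outlier spots per array against 21 to 54 on the others, stood apart, with all 6 of its block's pairs between 0.14 and 0.49. The 3 genes of the mock comparison became 0 with normexp, with a filter on all 12 arrays and with only the groups compared, 5 with median centring and with no filter, 17 with the authors' table values, 1 with trend and robust, and 1 with the scanner's median signal. With only the groups compared 8568 genes differed between genotypes with MeJA. Leaving out 1 array gave 2 to 1926 genes in the mock comparison, 2999 to 6004 between genotypes with MeJA, and 1338 to 3876 for the interaction. No alternative to scaling, filter or model turned the direction of a named gene's call. The size of the response was between -0.47 and -0.31 with 1 array left out and -0.20 with no minimum fold, with no permutation p under 0.05, and was not computed under the sample-record names, where no gene was called on average.

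DOF2.1 changed by 0.37 with MeJA in WT under the sample-record names and did not pass. With MeJA the genotypes differed by -0.52 under them and by -2.35 on the 8 arrays, neither passing. With the authors' table values it fell to -0.68 with MeJA in dof2.1-KO and to -3.30 between genotypes in mock, both passing.

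Gene lists called by camera fell with an estimated correlation to 1 for MeJA in WT, 2 in dof2.1-KO, 0 in mock, 0 between genotypes with MeJA, 0 for the interaction and 1 on average, and fry gave 0 in mock and 4 for the interaction. The sample-record names gave 7 in dof2.1-KO and 7 for the interaction, and the 8 arrays 7 for the interaction. Leaving out 1 array gave 5 to 11 in mock and 7 to 13 for the interaction. Marker lists called for MeJA in WT were 5 with fry, 3 with no filter, 0 under the sample-record names and 1 to 2 with 1 array left out. In dof2.1-KO they were 1 with an estimated correlation, 5 with fry, 1 under the sample-record names, 1 on the 8 arrays and 1 to 3 with 1 array left out. Between genotypes with MeJA they were 0 with an estimated correlation, 2 with fry and 2 with no filter, for the interaction 0 with an estimated correlation, and on average 4 with fry, 2 with normexp, 2 with quantile normalization, 3 with no filter and 1 to 3 with 1 array left out.

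Among named genes and lists called under at least 1 setting, directions turned almost only under the sample-record names, where none of these genes passed. For MeJA in dof2.1-KO these were JAZ2 -0.30, NYE1 -0.51, PAO -0.44, ABI1 -0.26 and FDH 0.023. Between genotypes with MeJA they were BSMT1 3.20, AT4G10290 1.32, JAZ10 0.94, JAZ9 0.59, JOX1 3.07, JR1 2.27, KAT2 0.21, ORE1 0.38, WRKY57 0.57, PAO 0.31, PPH 0.81, NYC1 0.10, RBCS2B -0.46, RBCS3B -0.53, ABI1 0.87, PAP2 4.50, ATML1 -0.28 and FDH -0.74. Lists called under at least 1 set of names whose camera direction turned had these medians. MeJA in WT: ERF branch -2.23, leaf senescence -0.11, heat shock -0.60. MeJA in dof2.1-KO: JAZ repressors 0.30, leaf senescence -0.32, chlorophyll breakdown -0.38, autophagy -0.29. Genotypes in mock: jasmonate biosynthesis 1.01, JAZ repressors 1.91, MYC branch 2.41, ERF branch -0.11, chlorophyll breakdown 1.22, chlorophyll synthesis -1.20, light harvesting complexes -0.88, photosystems -0.89, indole glucosinolates 0.26, flavonoids 3.76, cytokinin response regulators -3.6, cell division 0.22. Genotypes with MeJA: jasmonate biosynthesis 0.90, JAZ repressors 1.13, MYC branch 1.43, leaf senescence 0.41, chlorophyll breakdown 0.35, chlorophyll synthesis -1.04, photosystems -0.86, flavonoids 3.81, cytokinin response regulators -3.95. Some of these lists were not called under the series-table names but were called the other way under the sample-record names. For MeJA in WT these were all 3 lists, and in dof2.1-KO autophagy. In mock they were JAZ repressors, MYC branch, chlorophyll breakdown and synthesis, light harvesting complexes, photosystems and flavonoids. With MeJA they were chlorophyll synthesis, photosystems and cytokinin response regulators. Jasmonate catabolism in mock turned on the 8 arrays (-1.85), and the interaction of the photosystems list with quantile normalization (0.16).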

Other observations

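The groups below were fixed before any value was seen, and the hypotheses were written after the results had been seen. Some clock genes changed with MeJA, while camera did not call the list (adjusted p = 0.29 in WT and 0.341 in dof2.1-KO). In WT 6 of 13 rose and 3 fell (median log2 0.36), with CCA1, a morning gene, at -2.64, LHY at -2.52, PRR5 at 3.32 and ELF4 at 3.12. In dof2.1-KO 7 rose and 4 fell (median 0.88, mean 0.15), with CCA1 at -3.37 and LHY at -3.35. The hour of harvest is not given in the sources used here. With MeJA 2 clock genes were lower in dof2.1-KO than in WT, and none had an interaction called. Autophagy genes had 8 of 15 higher with MeJA in WT (median 0.54; ATG8G 2.1, ATG8B 1.78; camera adjusted p = 0.0351, or adjusted p = 0.573 with an estimated correlation), and 5 higher and 4 lower in dof2.1-KO (ATG8B 1.61). With MeJA 4 were lower in dof2.1-KO (5 over the list alone), and 1 had a negative interaction (3 over the list alone).

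Heat shock genes had 2 of 7 higher and 3 lower with MeJA in WT (median 0.81, mean -0.21; HSP18.2 1.41, HSFA2 -3.09), and 2 higher in dof2.1-KO (HSP70-4 2.36); 2 were lower in dof2.1-KO with MeJA (HSP18.2 -1.75), and the interaction was called for 1 each way. Of the reference genes often used for scaling 1 of 7 rose and 2 fell with MeJA in WT, ACT2 (-1.13) among them with 1 mock array left by outlier spots, and 1 fell in dof2.1-KO (0 over the list alone). Their median was -0.21 in WT and -0.24 in dof2.1-KO. Of the root markers PYK10, a beta-glucosidase gene that jasmonate is known to induce in leaves, rose at least 376-fold in WT; WOX5 did not pass. Flower markers had 1 of 4 lower with MeJA in each genotype, AG, and no shoot meristem marker was measured.

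With MeJA the 4 phloem markers, the phloem DOF genes DOF5.6 (-2.54) and DOF5.3 (-2.45) and 11 of 19 cell division genes were lower in dof2.1-KO. With an estimated correlation neither list was called (adjusted p = 0.101 for phloem and 0.574 for cell division). No xylem marker passed between the genotypes with MeJA, and the cell division interaction was not negative on every slide. One hypothesis is that vascular tissue grows less under MeJA in dof2.1-KO. Counts of vein cells in stained leaf sections of both genotypes after MeJA would test it: equal counts would speak against it. A second hypothesis is that the defensin rise depends on the loss of DOF2.1. PDF1.2a measured by RT-PCR in a second mutant allele and in a line with DOF2.1 put back would test it: a rise that stays in the restored line would speak against it. With MeJA the phloem median was -0.68 under the sample-record names of 4 arrays, and PDF1.2a was 8.75 higher in dof2.1-KO (adjusted p = 0.0144). Under those names WT MeJA 2 and 3 are the arrays that the series table names dof2.1-KO mock, with PDF1.2a at -2.73 and -2.49. Both results may thus set dof2.1-KO MeJA mostly against dof2.1-KO mock, and they say little about genotype.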
